A study of Rattus norvegicus with 998 samples.

How the data were processed

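Gene expression was measured by targeted RNA sequencing (the TempO-Seq rat S1500+ assay, which counts ligated detector probes for a selected set of genes and not whole transcripts) in tissues of male and female Sprague Dawley rats given 7:3 fluorotelomer alcohol (7:3 FTOH) by gavage for 5 days, or the vehicle 1,2-propylene glycol. The labels give 8 doses, 0.05, 0.5, 1.7, 5, 16.7, 50, 167 and 500 mg/kg/day, and 12 tissues, of which 9 came from both sexes, ovary and uterus from females and testis from males. The deposited files are 21 tables of raw read counts per probe, 1 for each tissue and sex; the authors aligned the reads with HISAT2, for which the labels state no version, and applied no scaling. Each tissue of each sex has its own plate number in its library names, so plate and sex cannot be separated within a tissue.

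The tables hold 998 libraries from 95 animals and 2654 probes for 2603 gene symbols, 35 of which have several probes. Each line of the deposited tables repeats the whole probe list in place of a single probe name, so line i was taken as probe i of that list. This was checked with 13 probes for genes of known tissue, and 13 of the 13 had their highest median in the tissue named beforehand. Of the symbols, 2387 are current in the GRCr8 gene table and 101 are older synonyms there; probe positions are not in the files, so no coordinates are given. No column was left unused and no pair of library columns was identical. The 9 libraries to which the authors gave a quality label other than "No Issue" (6 outliers, 2 with low alignment and 1 with low depth) were left out, which leaves 989 with total counts of 427590 to 5768717 (median 1923713). Vehicle groups hold 8 animals and dose groups 5, with 4 males at 500 mg/kg/day; removed libraries lower these numbers in single tables.

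Each tissue and sex was fitted separately with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr on the dose group, robust glmQLFit on group means, and glmQLFTest of each dose against vehicle, two-sided. P values were adjusted by the Benjamini-Hochberg method over the probes tested in each contrast, and a call needs an adjusted p under 0.05. Counts are of probes, called genes where a gene has 1 probe. A dose trend was tested as 1 slope over the ordered dose groups. Benchmark doses were fitted to log2 CPM (counts scaled to the library total, prior count 2) of the trend genes with linear, power, Hill and saturating exponential curves (exponents of the power and Hill curves from 1 to 4), the best by AIC. The benchmark dose is where the curve departs from its value at dose 0 by 1 residual standard deviation. Values under 0.05 mg/kg/day are given as under the lowest dose, and medians need at least 10 genes, or 3 for a gene list; their intervals come from 100 bootstrap resamples of animals within doses. The trend genes were chosen once from all libraries used and kept in the resamples and in every refit of the curves. The study's own summary by GO class was not analysed here.

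The 40 gene lists (targets of nuclear receptors and stress pathways, metabolic pathways, and markers of cell types that the tissues could hold) were fixed before the data were examined. Each was tested at 500 mg/kg/day with limma 3.58.1 camera at a preset correlation of 0.01, where at least 3 members were tested, and again with an estimated correlation; list p values are adjusted over the lists of that tissue and sex, and members are counted as probes. The difference of the 500 mg/kg/day effect between sexes, and between liver and kidney, was tested as an interaction in edgeR. The animal numbers pair the liver and kidney libraries, so the second test was repeated with animal as a block.

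The genes named follow a rule fixed beforehand. In the liver of each sex it takes the 10 largest increases and decreases among calls with all animals at 500 mg/kg/day on the same side of the vehicle mean and a mean log2 CPM of at least 3, and 3 called members of each called list. It takes the 5 largest each way in kidney and the 2 largest in other tissues. It adds 12 genes followed over all doses in liver (10 reported), the smallest p values of the interactions, and the 3 lowest benchmark doses in liver of each sex. Of the genes that this rule takes, 4 are not reported here. Other list members and genes called in many tissues were named after their values were seen. Errors are standard errors (SE) of the fitted log2 fold change, or standard deviations (SD) of log2 CPM between animals.

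On simulated data built from male liver counts, edgeR recovered 56.1% of 2-fold and 90% of 4-fold changes with 7 false calls among 152, and 0 calls where nothing was changed. In female thymus the shares were 70.7% and 97%. The tests of a difference recovered less at 2-fold, 29.3% between sexes and 17.5% between tissues. With animal as a block the share between tissues was 36.1%, with 7 false calls among 113, against 0 false calls among 82 without the block. The simulated counts held no differences between runs of animals and no RNA of other tissues. The rates of false calls thus need not hold for the real libraries.

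Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a 1.5-fold minimum, the probes of a gene summed, vehicle and 500 mg/kg/day libraries alone, all libraries kept, each 500 mg/kg/day animal left out in turn, dose on a log scale, the 500 mg/kg/day group left out, and other curve settings. After the data were seen, refits were added without libraries rich in markers of another tissue (a list mean over 5 median absolute deviations and over 1.5 log2 units above the median of the table), without female animals r81 to r88, and with 0.05 mg/kg/day as the reference. Counts at 500 and 50 mg/kg/day, trends and interactions were compared with regroupings of the same libraries (40, or 25 for interactions, the real grouping included). Other statistics and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.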

Results

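The data are targeted counts for 12 tissues of male and female rats after 5 days of oral dosing with 7:3 fluorotelomer alcohol, a polyfluorinated alcohol with a short hydrocarbon link to its fluorinated chain. The question behind the design is at which dose, and in which tissues, gene activity begins to change. In the 989 libraries used, vehicle groups held 8 animals and dose groups 5, except 4 males at 500 mg/kg/day. At that dose male brain and testis were left with 3 animals, and the vehicle group of male lung with 7. Total counts ranged from 427590 in an ovary library to 5768717 in a male heart library, and the median was 1267300 in female liver and 1313994 in male liver. Animal numbers rise with dose within each sex, and each vehicle group is 1 unbroken run of 8 numbers. Values after ± are SE of the fitted log2 fold change unless called SD, and n = 5 females or 4 males at 500 mg/kg/day against 8 vehicle animals unless another n is given.

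The first comparison asks which tissues differ from vehicle at 500 mg/kg/day. Female thymus had the most calls, 634 of 2254 genes tested (353 higher, 281 lower), followed by female kidney with 526 of 2163 (299 higher, 227 lower) and male spleen with 428 of 2261 (223 higher, 205 lower). This order depends on single libraries: female thymus had 185 calls without r94 and 204 without libraries rich in markers of another tissue, and male spleen 205 without r44, while female kidney had 405 to 526 calls with 1 animal left out. Liver gave 285 calls of 1692 in females (156 higher, 129 lower) and 172 of 1638 in males (98 higher, 74 lower). Female thyroid had 15 calls, ovary 17 and female brain 22, while male brain had 6 and male thyroid 11. Uterus had 0 calls of 2162 with edgeR, 191 genes at an unadjusted p under 0.05, and 10 calls with DESeq2.

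**Figure D1:**
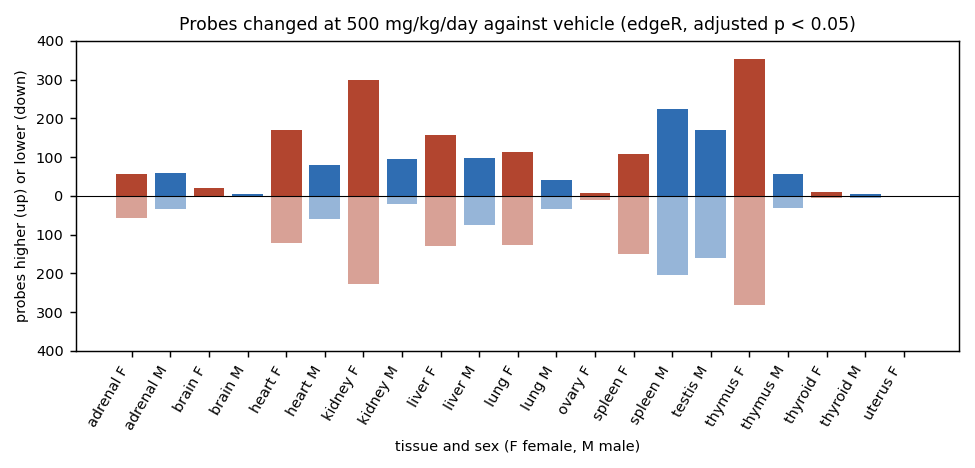
Number of genes called at 500 mg/kg/day against vehicle in each tissue and sex, with genes higher drawn upward and genes lower drawn downward from 0 (females red, males blue). Female thymus reaches 353 higher and 281 lower, and uterus has 0 of each.

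Liver was examined first, as the organ that an oral dose reaches first from the gut. In female liver at 500 mg/kg/day, genes of fatty acid breakdown rose. Acot1, an acyl-CoA thioesterase, rose by a log2 fold change of 7.60 ± 0.66 (adjusted p = 1e-11, higher in 5 of 5 animals), from 12 counts summed over the vehicle libraries, 3 of which held none, to 1223 counts over the dosed ones. Eci1 rose by 2.94 ± 0.30 (adjusted p = 2.86e-10, 5 of 5), from 6.46 to 9.33 log2 CPM, and Ech1 by 2.73 ± 0.25 (adjusted p = 1e-11, 5 of 5), from 7.19 to 9.79. The drug-metabolizing enzyme Cyp3a1 rose by 2.81 ± 0.32 (adjusted p = 6.14e-09, 5 of 5) from 7.58 ± 0.75 (SD) log2 CPM in vehicle. Other large increases in 5 of 5 animals were the steroid hydroxylase Cyp17a1 (3.12 ± 0.46, adjusted p = 1.39e-06), Acot4 (2.82 ± 0.32), the acute phase protein Orm1 (2.70 ± 0.37), Cyp3a23.3a1 (2.62 ± 0.43), Vnn1 (2.59 ± 0.26) and Acot2 (2.48 ± 0.42). Cyp3a1 and Cyp3a23.3a1 have separate symbols on the panel, but whether their probes measure separate genes was not checked. Both are counted in the list of CAR and PXR targets.

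Among the decreases in female liver, Srd5a1, a steroid 5-alpha reductase, fell by 2.67 on the log2 scale (SE 0.38, adjusted p = 8.67e-07, lower in 5 of 5 animals) from 10.23 ± 0.38 (SD) log2 CPM in vehicle. The flavin monooxygenase Fmo1 fell by 2.54 (SE 0.38, adjusted p = 1.6e-06) and the sulfotransferase Sult1c3 by 2.34 (SE 0.53, adjusted p = 0.00118). LOC688090 fell by 4.95 (SE 1.25, adjusted p = 0.00414), from 293 counts over the vehicle libraries to 4. LOC100910229, MGC108823, Nrep and Aldh4a1 changed by -2.26 to -1.92, and all of these decreases were seen in 5 of 5 animals. Stac3 (-2.22, adjusted p = 0.0282) was no longer called without r92, r93, r94 or r95 (0.0587, 0.0695, 0.0835 and 0.0784), and Mest (-2.11) without r94 or r96 (0.0536 and 0.0645). The total of 285 calls became 188 without r94.

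Several gene lists moved in female liver. Of 24 PPAR alpha targets tested, 15 rose (16 adjusted over the list alone), with an adjusted p = 2.86e-15 for the list, and adjusted p = 0.000688 with an estimated correlation. Acaa1a rose by 2.08 ± 0.27 and Fabp1 by 0.87 ± 0.18, both in 5 of 5 animals. Of 15 targets of the xenobiotic receptors CAR and PXR, 9 rose (10 adjusted over the list alone), among them Ugt1a1 (2.02 ± 0.23) and Aldh1a1 (1.88 ± 0.22), while Cyp2b2 and Cyp2b3 fell by 0.72 and 0.73; the list gave an adjusted p = 1.41e-07 and adjusted p = 0.000688 with an estimated correlation. Mitochondrial fatty acid oxidation had 5 of 13 genes higher, 8 adjusted over the list alone, including Decr1 (1.94 ± 0.23) and Acaa2 (1.73 ± 0.19), with an adjusted p = 1.53e-05 and adjusted p = 0.0344 with an estimated correlation. Of 14 NRF2 targets 5 rose, also 5 adjusted over the list alone (adjusted p = 0.0116, and adjusted p = 0.024 with an estimated correlation): Akr7a3 by 1.64 ± 0.26, Hmox1 by 0.79 ± 0.22, and Gpx2 by 3.59 ± 0.76 in 4 of 5 animals from 15 counts over the vehicle libraries. The steroidogenesis genes Cyp17a1, Star (0.84 ± 0.19) and Cyp11a1 (0.42 ± 0.15) made up 3 of 4 tested (3 adjusted over the list alone, adjusted p = 0.00503, and adjusted p = 0.0344 with an estimated correlation); Cyp11a1 was no longer called without r94, r95 or r96 (0.107, 0.0659 and 0.398). Of 15 cholesterol genes 3 rose, Tm7sf2 (1.13 ± 0.21) and Fdps (0.81 ± 0.23) among them (3 adjusted over the list alone, adjusted p = 0.00675 for the list, but adjusted p = 0.433 with an estimated correlation). Cell cycle genes had 2 of 12 higher, 5 adjusted over the list alone (adjusted p = 0.0162, and adjusted p = 0.39 with an estimated correlation).

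Male liver shared the fatty acid response at 500 mg/kg/day, and lost expression of genes that male liver normally carries. Acot2 rose by 2.98 ± 0.36 (adjusted p = 7.81e-08, higher in 4 of 4 animals) from 3.88 ± 0.56 (SD) log2 CPM, and the fatty acid transporter Cd36 by 2.83 ± 0.36 (adjusted p = 1.76e-07, 4 of 4). The efflux pump Abcc3 rose by 2.82 ± 0.44 (adjusted p = 1.06e-05, 4 of 4), Ugt2b10 by 2.02 ± 0.42 (adjusted p = 0.000683, 4 of 4) and Eci1 by 1.90 ± 0.26 (adjusted p = 6.35e-07, 4 of 4). Carbonic anhydrase Car3 fell by 2.92 (SE 0.60, adjusted p = 0.000669), the bile acid carrier Slc10a2 by 2.90 (SE 0.56, adjusted p = 0.000317), the major urinary protein gene LOC259245 by 2.12 (SE 0.47, adjusted p = 0.00149), MGC108823 by 1.81 (SE 0.43) and Slc13a4 by 1.79 (SE 0.33), each in 4 of 4 animals. LOC259245 held 939408 counts over the vehicle libraries and 135574 over the dosed ones.

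Other large changes in male liver were no longer called with 1 animal left out. Without r46 the change became smaller for the 2 probes of Sult2a6 (2.59 to 1.84 ± 0.57, adjusted p = 0.0525, and 2.05 to 1.19 ± 0.43, adjusted p = 0.0925), Sult2a2 (2.35 to 1.27 ± 0.44, adjusted p = 0.0811) and Igfbp1 (2.13 to 0.81 ± 0.56, adjusted p = 0.492). In the decreases the fold stayed within its SE and the SE grew with 3 animals: Mt1a (-4.16 ± 1.14) was -4.25 ± 1.33 and Stac3 (-3.04 ± 0.81) -2.66 ± 0.84 without r46 (0.0536 and 0.0543). Cyp2c13 (-4.10 ± 1.27, adjusted p = 0.0295) gave 0.114, 0.0934 and 0.0964 without r46, r47 or r48, at -3.80 to -3.77, and Acsm3 (-1.88) gave 0.0509, 0.0772 and 0.0747 without r44, r46 or r48, at -1.91 to -1.76. Gadd45g (-2.12) gave 0.126, 0.0543, 0.124 and 0.117 without r44, r46, r47 or r48, at -2.64 to -1.96. The total of 172 calls fell to 75 without r46.

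In male liver 12 of 24 PPAR alpha targets rose (14 adjusted over the list alone, adjusted p = 1.74e-11, and adjusted p = 0.00154 with an estimated correlation). Of 8 probes for genes known to be higher in male than in female rat liver, 6 fell (8 adjusted over the list alone, adjusted p = 2.28e-07, and adjusted p = 0.0183 with an estimated correlation). Of these, Rgn fell by 1.00 (SE 0.22) in 4 of 4 animals, Obp3 by 1.60 (SE 0.40) at 1 probe and 1.61 (SE 0.42) at another, with 0.0525 and 0.0661 without r46, and Cyp2c11 by 1.38 (SE 0.39), with 0.0589 without r46. Of 16 CAR and PXR targets 8 rose and 1 fell (10 and 2 adjusted over the list alone, adjusted p = 4.55e-06, and adjusted p = 0.0342 with an estimated correlation), among them Cyp3a1 (1.73 ± 0.25) and Ugt1a1 (1.23 ± 0.23), both in 4 of 4. Mitochondrial fatty acid oxidation had 4 of 12 higher, 5 adjusted over the list alone, including Decr1 (1.2 ± 0.23), and Cpt2 (0.99), which gave 0.0919 without r46; its adjusted p = 0.00382, and adjusted p = 0.0433 with an estimated correlation. Cholesterol synthesis had 8 of 15 higher and 8 adjusted over the list alone, with Sqle at 1.45 ± 0.27, Idi1 at 1.46 ± 0.34, and Cyp51 at 0.76 in 3 of 4 animals (0.123 without r47); its adjusted p = 6.63e-05, but adjusted p = 0.199 with an estimated correlation.

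A further question was at which dose known liver targets first respond. Of the genes chosen for this, Cpt1a, Pdk4 and Angptl4 have no probe on the panel, and Cyp7a1 had too few counts to be tested in either sex. In female liver at 167 mg/kg/day Acot1 was 4.70 above vehicle (adjusted p = 1.13e-05), Cyp3a23.3a1 1.66 (adjusted p = 0.0102), Cyp4a1 1.13 (adjusted p = 0.000415) and Ehhadh 1.01 (adjusted p = 0.00459). Of these 5 animals 2 belong to the run of animal numbers r81 to r88 described with the dose series; without the run (n = 3) Acot1 was 3.67 ± 0.81 (adjusted p = 0.00292), Cyp3a23.3a1 1.63 ± 0.52 (adjusted p = 0.0355) and Cyp4a1 0.90 ± 0.26 (adjusted p = 0.0194), while Ehhadh was 0.58 ± 0.28 and no longer called (adjusted p = 0.183). At 500 mg/kg/day Cyp4a1 reached 2.12 ± 0.22 (adjusted p = 2.86e-10) and Ehhadh 1.93 ± 0.24 (adjusted p = 3.08e-08) in 5 of 5 animals. Cyp1a1 was not called (-1.20 ± 0.91, adjusted p = 0.394). In male liver Cyp4a1 (2.48 ± 0.31, adjusted p = 1.26e-07), Ehhadh (2.06 ± 0.24, adjusted p = 7.81e-08) and Cyp3a23.3a1 (1.47 ± 0.28, adjusted p = 0.000237) were called at 500 mg/kg/day in 4 of 4 animals and at no lower dose. Cyp2b1 (0.36, adjusted p = 0.667) was not called there, and Acot1 and Cyp1a1 in males and Cyp2b1 in females were not tested for low counts.

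**Figure D2:**
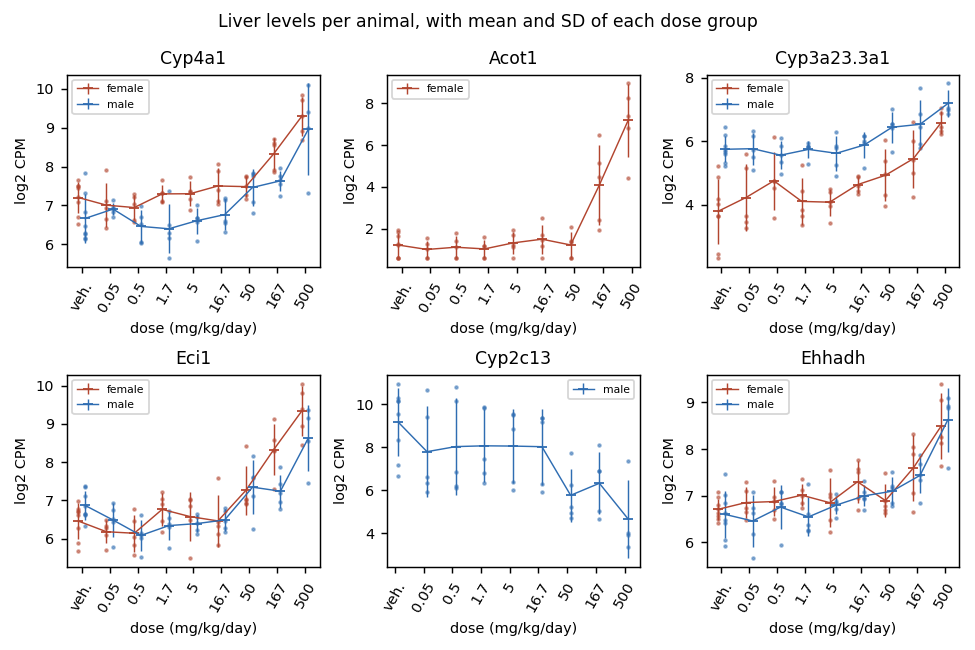
Log2 CPM of selected liver genes in each animal (points) against dose group in mg/kg/day (evenly spaced, vehicle at the left), with group means and SD, in females (red) and males (blue). Acot1 is drawn for females alone and Cyp2c13 for males alone. Cyp4a1 in females stands 1.13 above vehicle at 167 mg/kg/day and 2.12 at 500 mg/kg/day.

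Over the whole dose series, liver calls rose with dose in females: 3, 3, 4, 2 and 3 genes from 0.05 to 16.7 mg/kg/day, then 32 at 50, 153 at 167 and 285 at 500. DESeq2 gave 57 at 50, 176 at 167 and 335 at 500. All 5 animals at 50 mg/kg/day and 2 of those at 167 belong to a run of animal numbers, r81 to r88, that differs from the others in several tissues at any dose, liver included, so the 32 calls do not by themselves show a response to 50 mg/kg/day. Without that run 189 genes were called in female liver at 167. Male liver had 2 to 10 calls up to 50 mg/kg/day, 19 at 167 and 172 at 500. Female heart, with 1 to 21 calls below 500 mg/kg/day and 293 there, and male heart, with 0 to 7 and then 138, changed at the highest dose. Other series did not rise with dose. Testis had 111 to 237 calls at every dose below 500 mg/kg/day, of which 152 at 0.05, and 332 at 500. At 50 mg/kg/day female lung had 696 calls, ovary 493, thymus 404 and kidney 201, against 38, 1, 14 and 34 at 167. Female adrenal had 107 calls at 1.7 mg/kg/day, where the library of r68 carried smooth muscle markers 3.43 log2 units above the table's median, and male brain had 103 at 16.7, where that of r31 carried T-cell markers 5.99 above it.

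**Figure D3:**
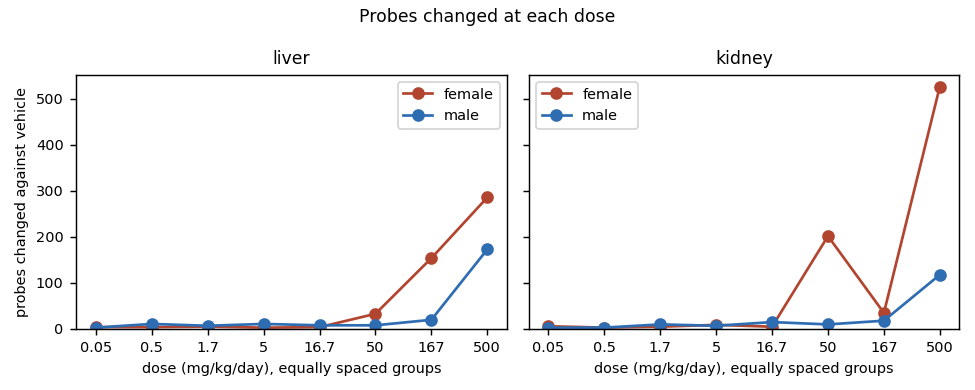
Number of genes called against vehicle at each dose (mg/kg/day, evenly spaced groups) in liver and kidney of females (red) and males (blue). Female liver climbs to 285 genes at 500 mg/kg/day, while female kidney has 201 at 50, 34 at 167 and 526 at 500.

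Whether the liver response differs between the sexes was tested as the difference of the 2 effects. It was past the threshold for 138 of 1772 genes, of which 66 had the higher effect in males and 72 in females. Sult1c2, a sulfotransferase, rose by 2.18 in females (adjusted p = 0.000376) and fell by 1.37 in males (adjusted p = 0.013, 0.059 without r46), a difference of -3.56 ± 0.59 (adjusted p = 1.93e-05). The clotting factor gene F10 fell by 1.27 in males and did not pass the test in females (0.39), with a difference of -1.67 ± 0.24 (adjusted p = 9.95e-07). LOC259245 differed by -2.50 ± 0.48 (adjusted p = 0.000368), Rps19 by -1.40 ± 0.27 (adjusted p = 0.000368), and LOC688090, too low to be tested in male liver alone, by 8.92 ± 1.39 (adjusted p = 7.28e-06). Calls of LOC688090 in male kidney, lung, spleen and thymus ended without r44, and its liver difference without that animal is not given here. With vehicle and 500 mg/kg/day libraries alone, the count was 75, 78 and 72 without r44, r46 or r47, 84, 76 and 68 without r94, r95 or r96, and 233 without r92. Plate and sex coincide within a tissue, so a plate effect on the dosed animals alone cannot be separated from sex.

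Kidney was the next question, since it excretes such compounds. In female kidney at 500 mg/kg/day the transcription factor genes Fosl1 and Atf3 rose by 6.44 ± 0.51 (adjusted p = 2.11e-13) and 3.85 ± 0.34 (adjusted p = 2.98e-12). The interferon-induced Rsad2 rose by 3.40 ± 0.32 (adjusted p = 1.43e-11) and Akr1b8 by 2.89 ± 0.59 (adjusted p = 0.000289). Noc2l fell by 3.22 (SE 0.41, adjusted p = 8.01e-08), Sult1c2 by 1.77 (SE 0.29, adjusted p = 1.54e-05), Gjb1 by 2.68 (SE 0.74, adjusted p = 0.00647) and Thrsp by 4.10 (SE 1.16, adjusted p = 0.00815). All of these held in 5 of 5 animals, and Gdpd3 (-2.89, adjusted p = 0.0182) gave 0.0577 without r94. The vehicle library of r53, which carried adipocyte markers 2.88 log2 units above the median, was the highest of its group for Thrsp and Gdpd3.

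Of the gene lists in female kidney, 13 of 25 PPAR alpha targets rose (13 adjusted over the list alone, adjusted p = 1.08e-09, and adjusted p = 0.00849 with an estimated correlation), among them Vnn1 (2.44 ± 0.23), Acaa1a (2.26 ± 0.15) and Ehhadh (1.57 ± 0.18). The NRF2 list had 11 of 15 higher and 1 lower (adjusted p = 5.48e-07, and adjusted p = 0.00507 with an estimated correlation), with Gstp1 at 2.33 ± 0.19, Srxn1 at 2.12 ± 0.26 and Hmox1 at 2.02 ± 0.28. CAR and PXR targets had 9 of 14 higher (10 adjusted over the list alone, adjusted p = 5.13e-06, and adjusted p = 0.00507 with an estimated correlation), including Ugt2b1 (3.50 ± 0.63) and Ephx1 (2.03 ± 0.14). In the unfolded protein and ATF4 list 6 of 12 rose and 2 fell (adjusted p = 0.000251, and adjusted p = 0.0122 with an estimated correlation): Trib3 rose by 3.88 ± 0.61 and Ddit3 by 1.05 ± 0.17, while Hsp90b1 fell by 0.62 (SE 0.20). Cholesterol synthesis had 9 of 14 higher (adjusted p = 0.000206, but adjusted p = 0.198 with an estimated correlation) and the kidney injury markers 3 of 7, Spp1 at 2.13 ± 0.31 and Timp1 at 1.10 ± 0.14 among them (adjusted p = 0.0271, but adjusted p = 0.198 with an estimated correlation). Each gene given here changed in 5 of 5 animals.

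Male kidney gave 96 higher and 21 lower of 2148. Atf3 rose by 4.33 ± 0.49 (adjusted p = 6.72e-08), the heat shock gene Hspb1 by 3.22 ± 0.45 (adjusted p = 4.16e-06) and Rsad2 by 3.08 ± 0.44 (adjusted p = 4.16e-06), each in 4 of 4 animals. Gap43 fell by 1.37 (SE 0.22, adjusted p = 4.26e-05) and Snap25 by 1.14 (SE 0.15, adjusted p = 1.21e-06), both in 4 of 4. Single animals carried 2 increases: LOC688090 (5.57) became 0.02 ± 1.32 without r44 (0.997), and Car3 (5.48) 0.97 ± 1.71 without r48 (0.825), whose library held adipocyte markers 2.76 log2 units above the median. Other calls ended with 3 animals while the fold changed little: Txlnb (-1.20) gave 0.0696 and 0.0862 without r46 or r48, at -1.20 and -1.03, Npas2 (-1.13) 0.183 and 0.0862, at -0.89 and -1.01, and Thy1 (-1.15) 0.0699, 0.25, 0.0659 and 0.0862 without r44, r46, r47 or r48, at -1.22 to -1.02. Cholesterol synthesis was higher in 9 of 15 genes (11 adjusted over the list alone, adjusted p = 2.94e-11, and adjusted p = 0.0331 with an estimated correlation), with Insig1 at 1.45 ± 0.18 and Idi1 at 1.07 ± 0.17. PPAR alpha targets were higher in 8 of 24, also 8 adjusted over the list alone (adjusted p = 1.62e-07, but adjusted p = 0.0681 with an estimated correlation), with Ehhadh at 1.45 ± 0.22. The total of 117 calls became 39 without r46 and 75 without r48, and 10 with vehicle and 500 mg/kg/day libraries alone.

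Liver and kidney came from the same animals, and whether the 500 mg/kg/day effect differs between them was tested with 101 calls in females (38 with the higher effect in liver, 63 in kidney) and 84 in males (31 and 53). With animal as a block, the counts were 99 and 60, of which 82 and 50 were in both fits. In females Acot1 rose by 7.42 ± 0.66 more in liver (adjusted p = 3.94e-15; 6.97 with the block). Sult1c2 rose by 2.18 in liver and fell by 1.77 in kidney, a difference of 4.00 ± 0.52 (adjusted p = 1.26e-08; 4.01 with the block). In males Acot1, too low to be tested in male liver alone, differed by 6.68 ± 0.79 (adjusted p = 1.85e-09), and by 4.81 with the block (adjusted p = 0.00127). Abcc3 differed by 2.85 ± 0.50 (adjusted p = 0.000121, and 2.77 with the block) and the cell cycle gene Rb1 by -1.21 ± 0.18 (adjusted p = 3.49e-06, and -1.22 with the block). The male count became 25 without r46 and 41 without r48.

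In female heart at 500 mg/kg/day, genes of several stress pathways rose. There the metallothionein gene Mt2a rose by 4.84 ± 0.54 (adjusted p = 1.99e-08) from 3.93 ± 0.61 (SD) log2 CPM, and Fosl1 rose by 4.71 ± 0.76 (adjusted p = 1.41e-05), both in 5 of 5 animals. Alox15 fell by 2.77 (SE 0.73, adjusted p = 0.00797) in 5 of 5, and LOC688090 fell by 5.64 but gave 0.0603 and 0.0545 without r92 or r96. The unfolded protein and ATF4 list (8 of 12, 9 adjusted over the list alone, adjusted p = 1.17e-05), glucocorticoid response (4 of 4, adjusted p = 1.17e-05) and NRF2 list (5 of 16, 6 adjusted over the list alone, adjusted p = 0.000146) were higher, each with adjusted p = 0.0318 with an estimated correlation. Among their genes Nqo1 rose by 2.26 ± 0.42, Hmox1 by 2.22 ± 0.30, Mt1a by 2.19 ± 0.47 and Asns by 2.04 ± 0.35. The 293 female calls became 192 without r92 and 185 without r96. In male heart Fosl1 rose by 5.27 ± 0.83 (adjusted p = 4.44e-05) and Mt2a by 3.89 ± 0.58 (adjusted p = 2.17e-05), both in 4 of 4, and the glucocorticoid list had 2 of 4 higher and 4 adjusted over the list alone (adjusted p = 2.22e-06, and adjusted p = 0.00708 with an estimated correlation), Cebpd among them at 1.71 ± 0.24. Crp and Cyp3a2 fell by 7.07 and 6.78 and hepatocyte markers fell in 5 of 10 probes (8 adjusted over the list alone, adjusted p = 0.0272, but adjusted p = 0.578 with an estimated correlation), in a table where the vehicle library of r04 held hepatocyte markers 6.07 log2 units above the median. Crp gave 0.0981, 0.0569 and 0.146 without r46, r47 or r48, and Cyp3a2 0.0825 and 0.135 without r46 or r48. The 138 male calls became 42 without r46 and 16 without r48, and 5 with vehicle and 500 mg/kg/day libraries alone.

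In adrenal gland the question was whether hormone and sterol genes change. In males LOC259245 fell by 2.55 (SE 0.31, adjusted p = 4.55e-07) and Col3a1, a collagen gene, by 3.19 (SE 0.70, adjusted p = 0.00383), both in 4 of 4 animals. Nr4a3 rose by 3.37 ± 0.69 (adjusted p = 0.00242) and Ugt2b7 by 2.76 ± 0.59 (adjusted p = 0.00283), also in 4 of 4. Genes higher in male liver fell in 4 of 7 (5 adjusted over the list alone, adjusted p = 3.59e-08, and adjusted p = 0.0141 with an estimated correlation), Obp3 by 2.08 (SE 0.33) and Cyp2c11 by 1.73 (SE 0.28) among them. These and LOC259245 are genes of liver, and here 42 of 48 liver-specific probes fell, with vehicle levels that followed those of vehicle liver (r = 0.995 across genes), so a change within adrenal cells is not shown. Steroidogenesis genes rose in 2 of 4 in males (3 adjusted over the list alone, adjusted p = 0.00121, but adjusted p = 0.175 with an estimated correlation) and in 0 of 6 in females, whose list was not called (adjusted p = 0.101). Cholesterol synthesis was higher in 10 of 15 (13 adjusted over the list alone, adjusted p = 1.95e-15, but adjusted p = 0.0528 with an estimated correlation); Sqle rose by 1.47 ± 0.39 and gave 0.207 without r46. The 92 male calls became 41 without r46. In females Dbp rose by 2.24 ± 0.32 (adjusted p = 6.39e-06) and Cenpi by 2.05 ± 0.53 (adjusted p = 0.0115), and Slc7a12 fell by 1.83 (SE 0.30, adjusted p = 7.82e-05), each in 5 of 5. LOC688090 fell by 4.25 but gave 0.0671, 0.0714, 0.0547 and 0.0659 without r92, r93, r95 or r96. The female total was 113, with 57 higher and 56 lower. With the 0.05 mg/kg/day animals as the reference the totals were 35 in females and 23 in males.

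Brain had few calls. In females the chemokine gene Ccl2 rose by 4.34 ± 0.67 (adjusted p = 8.25e-05) and Noc2l fell by 2.96 (SE 0.44, adjusted p = 7.89e-05), both in 5 of 5 animals. Ccl7 rose by 3.74 but gave 0.246 without r94, and Cga, a pituitary hormone gene with 704 counts over the vehicle libraries and 1 over the dosed ones, fell by 7.74 and gave 0.146, 0.0644, 0.108, 0.065 and 0.0603 without r92, r93, r94, r95 or r96. Glucocorticoid response genes were higher in 3 of 4 (adjusted p = 3.14e-07, and adjusted p = 0.00557 with an estimated correlation), Mt2a at 2.14 ± 0.37 in 4 of 5 animals among them, and acute phase genes in 3 of 15, 6 adjusted over the list alone (adjusted p = 3.63e-06, and adjusted p = 0.0437 with an estimated correlation), Tnf at 2.27 ± 0.47 among them. The 22 female calls became 11 without r92 and 12 without r94. In males (n = 3) Lcn2 rose by 3.19 ± 0.57 (adjusted p = 0.00191, 0.334 without r46), Thrsp rose by 1.40 ± 0.30 (adjusted p = 0.0158, and 0.0924, 0.145 and 0.0549 without r46, r47 or r48) and Fbxo22 fell by 1.43 (SE 0.24, adjusted p = 0.00157, 0.0924 without r46). Without r46 the 6 male calls became 0 with edgeR.

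Lung of females had 112 genes higher and 128 lower of 2235, and of males 41 higher and 35 lower of 2195. Cyp2a3 rose by 3.14 ± 0.55 in females (adjusted p = 0.000198, 5 of 5 animals), and Pck1 by 2.99 ± 0.80 (adjusted p = 0.0155, 0.113 without r96). Col3a1 (-2.36) gave 0.0853, 0.0877, 0.0572 and 0.0916 without r93, r94, r95 or r96, and Plg (-1.52) 0.101, 0.0944, 0.0572 and 0.0967 without r92, r94, r95 or r96. The cell cycle gene Ccnb2 fell by 1.01 in females (SE 0.23, adjusted p = 0.00492, 5 of 5) and by 0.80 in males (SE 0.16, adjusted p = 0.00433, 4 of 4). Its list was lower in 3 of 20 genes in females (adjusted p = 0.000874, but adjusted p = 0.469 with an estimated correlation) and in 3 of 22 in males (5 adjusted over the list alone, adjusted p = 0.00635, but adjusted p = 0.456 with an estimated correlation). In males LOC688090 (3.77) gave 0.574 without r44, and the efflux pump Abcb1b (1.46) 0.169 and 0.0716 without r46 or r48. Col3a1 (-3.22) gave 0.128, 0.0789 and 0.0793 without r46, r47 or r48, and the hepatocyte marker Alb (-3.60) 0.1, 0.168, 0.102 and 0.0998 without r44, r46, r47 or r48. The female total of 240 became 107 without r92 and the male total of 76 became 28 without r44 and 18 without r46. With the 0.05 mg/kg/day animals as the reference the female total was 8.

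Spleen and thymus bear on immune effects of the compound. In male spleen the troponin gene Tnnc2 fell by 2.86 (SE 0.51, adjusted p = 0.000318) and Serpina3c by 2.55 (SE 0.36, adjusted p = 5.98e-06), and the complement gene C1qa rose by 1.94 ± 0.47 (adjusted p = 0.00423), each in 4 of 4 animals. Tnnc2 is a skeletal muscle marker, and 44 of 49 liver-specific probes also fell here, so a change within spleen cells is not shown for Tnnc2. Whether Serpina3c fell within spleen cells was not tested. LOC688090 (4.70) gave 0.931 without r44. Cell cycle genes fell in 13 of 23 (14 adjusted over the list alone, adjusted p = 4.92e-08, but adjusted p = 0.314 with an estimated correlation), Ccna2 by 1.68 (SE 0.41) and Birc5 by 1.39 (SE 0.29), and hepatocyte markers in 6 of 10 (7 adjusted over the list alone, adjusted p = 0.000237, but adjusted p = 0.433 with an estimated correlation). In female spleen Dao fell by 1.96 (SE 0.14, adjusted p = 3.6e-15) and the amino acid carrier Slc7a12 by 2.51 (SE 0.34, adjusted p = 5.84e-07), and LOC100360856 rose by 1.80 ± 0.39 (adjusted p = 0.00126), each in 5 of 5. Sult1c2 rose by 1.59 but gave 0.12 without r92. The male total of 428 became 205 without r44 and 263 without r48, and the female total of 258 became 135 without r92. With the 0.05 mg/kg/day animals as the reference they were 147 and 116.

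In female thymus Cyp2e1 rose by 4.52 ± 0.60 (adjusted p = 3.55e-06) and the muscle-type carnitine acyltransferase Cpt1b by 4.10 ± 0.68 (adjusted p = 0.000141), and Col3a1 fell by 2.13 (SE 0.55, adjusted p = 0.0045), each in 5 of 5 animals. Cell cycle genes fell in 18 of 23 (20 adjusted over the list alone, adjusted p = 1.5e-11, but adjusted p = 0.275 with an estimated correlation), among them Bub1b by 1.35 (SE 0.31), Mki67 by 1.15 (SE 0.23) and Ccnb2 by 1.10 (SE 0.24), and T-cell markers in 4 of 5 (adjusted p = 0.007, but adjusted p = 0.275 with an estimated correlation). Mt2a rose by 2.90 ± 0.35 and Mt1a by 1.64 ± 0.26 in 5 of 5. The library of r94 at 500 mg/kg/day held adipocyte markers 4.50 log2 units above the median, in a table where 9 of 10 adipocyte probes rose (adjusted p = 0.00103, but adjusted p = 0.422 with an estimated correlation), together with 13 of 21 PPAR alpha targets (adjusted p = 0.000242, but adjusted p = 0.275 with an estimated correlation) and 12 of 14 genes of mitochondrial fatty acid oxidation (adjusted p = 0.000242, but adjusted p = 0.411 with an estimated correlation). Without r94 the 634 calls became 185. Cyp2e1 was highest in r94 among the 500 mg/kg/day animals, and Cpt1b belongs to the fatty acid oxidation list that rose along with the adipocyte markers. A change within thymus cells is thus not shown for Cyp2e1 or Cpt1b. LOC688090 (-6.42) gave 0.084, 0.0632, 0.105, 0.0559 and 0.067 without r92, r93, r94, r95 or r96.

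Male thymus had 57 genes higher and 32 lower of 2421. Col3a1 fell by 5.17 (SE 0.83, adjusted p = 0.000219) in 4 of 4 animals, in a table where the vehicle library of r08 held smooth muscle markers 1.60 and adipocyte markers 3.69 log2 units above the median. The skeletal muscle marker Tnnc2 fell by 3.83 (0.0687 without r46), LOC680329 rose by 1.54 (0.184 and 0.142 without r46 or r47) and LOC688090 by 4.93 (0.752 without r44). Cell cycle genes fell in 2 of 23, 3 adjusted over the list alone (adjusted p = 0.000159, but adjusted p = 0.235 with an estimated correlation). The 89 calls became 17 without r46 and 59 without r48, and 5 with vehicle and 500 mg/kg/day libraries alone.

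Thyroid gland gave few calls with edgeR, and several times as many with DESeq2. Cyp2e1 rose in females by 2.53 ± 0.56 (adjusted p = 0.0194, and 0.0904 and 0.128 without r92 or r96) and in males by 1.99 ± 0.47 (adjusted p = 0.0304, and 0.329 and 0.12 without r46 or r48). Noc2l fell by 2.38 in females (SE 0.32, adjusted p = 3.97e-06) in 5 of 5 animals. Other calls ended with 1 animal fewer. In females LOC100909675 (1.43) was 1.02 ± 0.33 without r94 (0.196), and LOC100134871 (-2.62) gave 0.155, 0.089, 0.149 and 0.0708 without r92, r93, r94 or r95, at -2.63 to -2.48. In males Fkbp5 (1.27) was 0.95 and 1.38 without r46 or r48 (0.259 and 0.0733), and Ust4r (-3.33) gave 0.215, 0.0609 and 0.0757 without r46, r47 or r48, at -3.45 to -3.13. Of the lists called, 6 in females and 5 in males, 0 held with an estimated correlation, the glucocorticoid response in females (2 of 4 higher, adjusted p = 0.00209, but adjusted p = 0.123 with an estimated correlation) among them. The 15 female calls became 7 and 6 without r92 or r94, and the 11 male calls 1 and 0 (edgeR) without r46 or r48.

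The reproductive tissues were examined for changes in steroid genes, and the steroidogenesis list was not called in testis (0 of 7 higher and 1 lower, adjusted p = 0.2), ovary (0 of 7, adjusted p = 0.239) or uterus (0 of 4, adjusted p = 0.889). In testis (n = 3) the chemokine gene Ccl2 rose by 4.40 ± 0.37 (adjusted p = 2.12e-12) and Hpx by 4.02 ± 0.47 (adjusted p = 2.29e-08), and Tnnc2 fell by 4.98 (SE 1.02, adjusted p = 0.000489) and Amy2a3 fell by 4.47 (SE 1.05, adjusted p = 0.00216), each in 3 of 3 animals. Tnnc2 is a marker of skeletal muscle and Amy2a3 of exocrine pancreas, and 33 of 34 liver-specific probes fell in testis too. A change within testis cells is thus not shown for Tnnc2 or Amy2a3. Myeloid markers rose in 3 of 6 (adjusted p = 0.00835, but adjusted p = 0.0731 with an estimated correlation), Cd68 by 2.35 ± 0.27 among them, and acute phase genes in 7 of 17 (adjusted p = 0.00721, but adjusted p = 0.0731 with an estimated correlation). The 332 calls became 206 without r46, and 154 with the 0.05 mg/kg/day animals as the reference. In ovary Col3a1 fell by 3.73 (SE 0.51, adjusted p = 8.62e-06) and Daxx rose by 1.61 ± 0.22 (adjusted p = 4.19e-06), both in 5 of 5. Dbp rose by 1.11 (0.0801 without r94) and Cd53 fell by 1.28 (0.0536, 0.063, 0.0877 and 0.112 without r92, r94, r95 or r96). The 17 ovary calls became 4, 8, 10 and 7 without r92, r94, r95 or r96, and 2 with the 0.05 mg/kg/day animals as the reference. In uterus 0 genes were called with edgeR (10 with DESeq2, 191 at an unadjusted p under 0.05), and without r92, r93, r95 or r96 the count was 2, 3, 4 and 3.

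Some genes recurred across tissues at 500 mg/kg/day and were picked out after their values were seen. The tissues of each sex came from the same animals, so a repeat in another tissue is not independent evidence. The clock gene Arntl fell in 9 of 11 female tissues, by -1.30 to -0.64, in 5 of 5 animals each time; in ovary it gave 0.122, 0.122, 0.126 and 0.104 without r92, r94, r95 or r96, and in thymus 0.0703 without r94. Dbp, which the clock drives in the opposite phase, rose in 8 female tissues by 0.72 to 2.24, and its calls in heart (0.188 and 0.195 without r94 or r95), ovary (0.0801 without r94), thymus (0.0765 without r94) and thyroid (0.116 without r94) ended without 1 animal. In males Dbp rose in 5 tissues by 0.64 to 1.07, with 0.712 in liver, 0.15 in lung, 0.232 in thymus and 0.278 in thyroid without r46, and 0.0733 in thyroid without r48. Noc2l fell by -3.22 to -1.87 in female brain, heart, kidney and thyroid, with 5 of 5 animals below vehicle and a call without any 1 of them. Daxx rose in 5 female tissues by 0.66 to 1.61 and fell in 5 male tissues by -1.62 to -0.81; in female adrenal it gave 0.092 and 0.0765 without r92 or r93, in male liver 0.0861, 0.054 and 0.0728 without r46, r47 or r48, and in testis 0.0612 without r47.

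**Figure D4:**
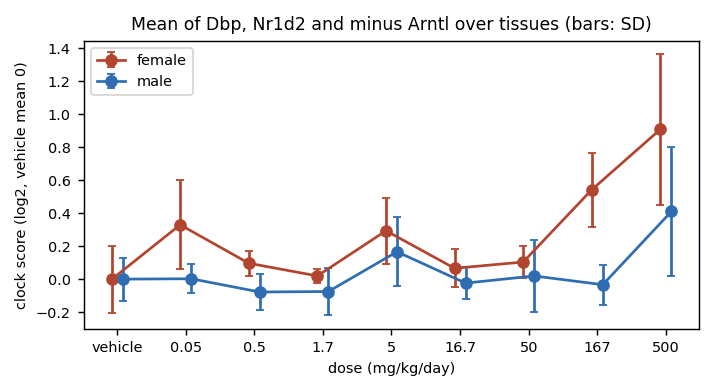
Mean change of the clock genes (Dbp and Nr1d2 up, Arntl down counted as positive; log2 units, averaged over tissues) against dose group in mg/kg/day, as group mean and SD over animals in females (red) and males (blue). The female mean is 0.91 at 500 mg/kg/day and 0.54 at 167, and the male mean is 0.41 at 500. At lower doses the female mean is 0.33 (SD 0.27) at 0.05 mg/kg/day, 0.295 (SD 0.20) at 5, and 0.021 to 0.11 at 0.5, 1.7, 16.7 and 50. The male mean lies between -0.076 and 0.17 at doses below 500.

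A test over all doses asked which genes follow the dose. Female liver had 366 such genes (212 rising, 154 falling) and male liver 164 (90 and 74), the largest counts in other tissues were 595 in female thymus, 460 in female kidney, 362 in testis and 340 in female spleen, and the smallest 3 in uterus. Without libraries rich in markers of another tissue female thymus had 325 and female kidney 441, so the order of these is not settled. The benchmark dose is the dose at which a fitted curve leaves its start by 1 SD between animals. Its median over genes was 62.3 mg/kg/day in female liver (33.6 to 78.5 in resampled animals, 353 genes) and 80.4 in male liver (39.6 to 107, 161 genes). With a 10% change as the response they were 17.3 and 23.5, and with Hill and linear curves alone 61.7 and 141, so the values hold for the chosen definition. In female liver CAR and PXR targets had a median of 48.5 (22.0 to 80.3, 11 genes) and PPAR alpha targets 107 (48.2 to 123, 17 genes), and in male liver 45.8 (12.8 to 163, 8 genes) and 127 (64.1 to 160, 12 genes); in each sex the 2 intervals overlap. Among the lowest values in liver, all under the lowest dose of 0.05 mg/kg/day, were those of Adipoq and Rasa1 in females and Col3a1, Daxx and Psat1 in males. Of these, Col3a1 fell by 1.77 at 500 mg/kg/day (adjusted p = 3.42e-06), while Adipoq (0.73, adjusted p = 0.0589) and Psat1 (-0.89, adjusted p = 0.0761) were not called there. Rasa1 (-0.56) gave 0.0616 without r95, and Daxx (-0.81) 0.0861, 0.054 and 0.0728 without r46, r47 or r48. Medians were 101 in female kidney (213 without r81 to r88) and 33.7 in male kidney (12.8 to 116; 11.1 with a 10% change and 16 without the 500 mg/kg/day group). In female thyroid the median was 1.42 (0.34 to 131 in resampled animals, 15 genes), and regroupings of the same libraries gave as many trend genes. That value was 10.9, 10.4 and 20.4 without r92, r94 or r96, 15.3 with Hill and linear curves alone and 16.9 without r81 to r88. The median was 5.76 in male thyroid and 1.21 in testis (0.683 to 5.42), where 131 of 359 genes lay under the lowest dose. In testis 5 bile acid genes such as Slco1b2 had a median under the lowest dose, with an interval from under the lowest dose to 0.77. In testis 33 of 34 liver-specific probes fell at 500 mg/kg/day, so a change within testis cells is not shown for these genes. In male thyroid the same genes had 5.77, and 3 genes higher in male liver had 3.25. Whether liver RNA enters the thyroid values was not tested. Testis already had 75 genes higher and 77 lower at 0.05 mg/kg/day. A difference of the run that forms the vehicle group could thus enter these low values.

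The calls at 50 mg/kg/day in female kidney, lung, ovary and thymus were compared across animals, a comparison chosen after the counts were seen. In at least 3 of these 4 tissues 228 genes were called, 93 higher and 135 lower. Each animal was scored by the mean log2 difference of these genes from vehicle, signed by the direction at 50 mg/kg/day and averaged over the 4 tissues. The 5 animals at 50 mg/kg/day had a mean score of 0.72 ± 0.045 (SD). The run of 8 numbers that holds them, r81 to r88, also holds 1 animal of 16.7 mg/kg/day (r81, 0.65) and 2 of 167 mg/kg/day (r87, 0.78, and r88, 0.64). The other 4 animals at 16.7 mg/kg/day scored 0.021 to 0.060, the other 3 at 167 mg/kg/day 0.0091 to 0.051, and all 40 animals outside the run -0.036 to 0.070. Within the run the 50 mg/kg/day animals differed from the other 3 by 0.033 (exact permutation p = 0.446, two-sided, 56 arrangements). Of the variance within doses, the run accounted for 0.967 (exact permutation p = 0.0008, 2500 arrangements). The same genes scored in the other 7 female tissues gave 0.837 (exact permutation p = 0.0064), with a mean of 0.15 at 50 mg/kg/day. In liver r81 to r88 scored 0.084 to 0.178 and the other animals -0.075 to 0.076, and in brain 0.305 to 0.371 and -0.049 to 0.115; female brain had 58 calls at 50 mg/kg/day and 1 at 167. Without r81 to r88, the ovary calls at 500 mg/kg/day became 31 and the ovary genes that follow the dose went from 117 to 3.

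**Figure D5:**
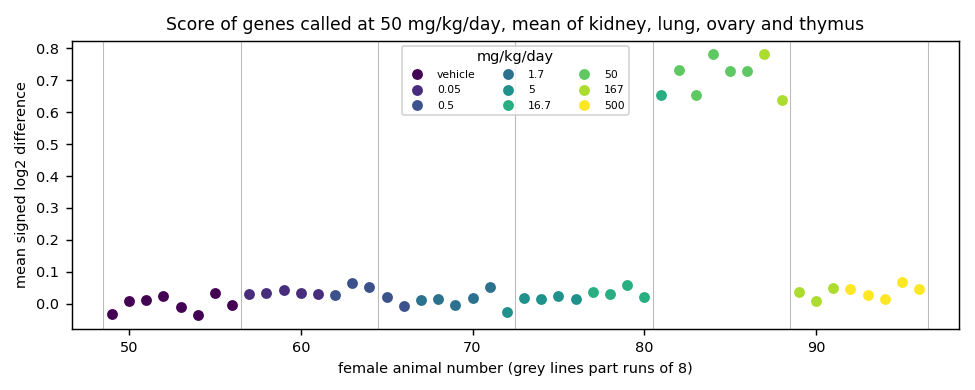
Score of each female animal on the 228 genes called at 50 mg/kg/day (vertical axis, mean signed log2 difference from vehicle over 4 tissues) against animal number, coloured by dose, with lines between runs of 8 numbers. The run r81 to r88 lies between 0.64 and 0.78, and the other animals between -0.036 and 0.070.

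The difference between the sexes at 500 mg/kg/day was tested in the other shared tissues too. Thymus had 267 genes (34 with the higher effect in males, 233 in females), heart 63, thyroid 49, spleen 40, kidney 29, adrenal 24, lung 4 and brain 2. Libraries with markers of another tissue enter some of these: the heart genes include those of hepatocytes, such as Alb (-7.26) and Apoa1 (-6.36), where the male vehicle library of r04 held hepatocyte markers 6.07 log2 units above the median, and in thymus adipocyte markers stood 4.50 above it in female r94 and 3.69 in male r08. The skeletal muscle marker Tnnc2 in thymus rose by 1.2 in females and fell by 3.83 in males (0.0687 without r46), a difference of -5.11 ± 0.88 (adjusted p = 0.000159). Noc2l differed by 3.27 ± 0.42 in kidney (adjusted p = 3.46e-08), 3.18 ± 0.52 in brain (adjusted p = 8.03e-05), 2.78 ± 0.34 in thyroid (adjusted p = 9.92e-09) and 2.37 ± 0.34 in heart (adjusted p = 1.41e-06). Dao in spleen fell by 1.96 in females and by 0.48 in males, with a difference of 1.45 ± 0.17 (adjusted p = 3.41e-09). Daxx in adrenal, rising in females and falling in males, differed by -1.90 ± 0.28 (adjusted p = 2.02e-06). With vehicle and 500 mg/kg/day libraries alone and any 1 of r44, r46 to r48 and r92 to r96 left out, the counts were 56 to 151 in thymus, 1 to 6 in heart, 13 to 32 in thyroid, 93 to 164 in spleen, 3 to 6 in kidney, 6 to 15 in adrenal, 0 to 9 in lung and 2 to 3 in brain.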

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

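The tests of the run of animal numbers and of a 50 mg/kg/day effect, and those of a single vehicle library and of lower liver expression, were chosen only after the results they explain were seen.

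In several groups of animals, 1 animal lay far from the rest for a gene named in the report. The values here are its gap to the nearest animal as a share of the whole range of the group, and each is above the critical value for a group of that size. Chance alone gives such a gap in about 1 in 20 groups. In female liver at 500 mg/kg/day, r93 was lowest for Aldh4a1 (0.807), r92 highest for Srd5a1 (0.792) and r96 highest for Stac3 (0.738), and in vehicle r54 was lowest for MGC108823 (0.699). In male liver at 500 mg/kg/day r44 was highest for Cyp2c13 (0.834) and lowest for Ehhadh (0.863) and Ugt2b10 (0.874), and r46 was highest for Igfbp1 (0.849) and Sult2a6 (0.914). Among male vehicle livers r07 was lowest for Acsm3 (0.578), r08 for Gadd45g (0.54) and r01 for Slc10a2 (0.658).

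In kidney the female vehicle animal r53 was highest for Fosl1 (0.61), Gdpd3 (0.674) and Thrsp (0.798), and its library also held adipocyte markers 2.88 log2 units above the median. In male kidney at 500 mg/kg/day r48 was highest for Car3 (0.847) and r44 for LOC688090 (0.873), and in vehicle r02 was highest for Hspb1 (0.583). Male heart vehicle r04 was highest for Crp (0.553) and Cyp3a2 (0.847), both genes of hepatocytes. In female brain r51 was highest in vehicle for Cga (0.584), and r96 highest at 500 mg/kg/day (1.0), where it held the only count of that gene. In adrenal, vehicle female r52 was lowest for Slc7a12 (0.623) and male r44 at 500 mg/kg/day lowest for LOC259245 (0.948).

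Among the remaining tissues, male lung vehicle r07 was lowest for Abcb1b (0.694) and r03 for Alb (0.61), ovary vehicle r56 was lowest for Dbp (0.621), and female spleen vehicle r49 was lowest for Dao (0.686) and highest for Sult1c2 (0.57). In female thymus at 500 mg/kg/day r94 was highest for Cyp2e1 (0.898), in male thymus vehicle r08 was highest for Col3a1 (0.556), and in female thyroid vehicle r54 was highest for LOC100134871 (0.664).

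Other results stood out because 2 sexes or 2 tissues differed in their response at 500 mg/kg/day by a test of the difference itself. As the male minus the female effect in log2 units, these were in adrenal Apoa1 (-1.60) and Daxx (-1.90), in brain Noc2l (3.18) and Fbxo22 (-1.79), in heart Noc2l (2.37) and LOC688090 (9.69), and in kidney Noc2l (3.27) and Snap25 (-1.23). In liver they were F10 (-1.67), LOC688090 (8.92), Sult1c2 (-3.56), Rps19 (-1.40) and LOC259245 (-2.50), and in lung Daxx (-2.93) and LOC259245 (-3.80). Spleen had Dao (1.45) and Hao2 (1.60), thymus Daxx (-3.07) and Tnnc2 (-5.11), and thyroid Noc2l (2.78) and LOC100909675 (-2.90). As the liver minus the kidney effect, they were Acot1 (7.42) and Sult1c2 (4.00) in females and Acot1 (6.68), Rb1 (-1.21) and Abcc3 (2.85) in males. Acot1 was too low to be tested in male liver alone. The calls of LOC688090 in male kidney, lung, spleen and thymus ended without r44.

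A first pattern is the large number of calls at 50 mg/kg/day in female kidney, lung, ovary and thymus, with few at 167. An effect of the 50 mg/kg/day dose alone is argued against: within the run r81 to r88, the 50 mg/kg/day animals differed from those at other doses by a share of only 0.0457 of the shift from vehicle. A technical difference between runs of 8 consecutive numbers stays open as a candidate explanation, since the run held 0.967 of the variance within doses, and 0.837 for the same genes in the other 7 female tissues. Library size stays open too, as the median total count at 50 mg/kg/day was 0.512 of that of the others in kidney, 0.30 in lung, 0.320 in ovary and 0.363 in thymus, so 0 of 4 tissues lay between 0.67 and 1.5. Since the vehicle animals also form 1 run, a difference of runs could enter other comparisons with vehicle as well.

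A second pattern is the change of clock genes at 500 mg/kg/day, Dbp and Nr1d2 higher and Arntl lower in several tissues. An order of the animals, such as the time of day at sampling, that follows the animal number cannot be told apart from dose. Over vehicle to 5 mg/kg/day the mean change followed animal number with Pearson r = 0.197 in females (permutation p = 0.317; Spearman rho 0.20, permutation p = 0.302; r = 0.301 without the 2 farthest animals) and r = 0.211 in males (permutation p = 0.285; rho 0.135, permutation p = 0.492; r = 0.262 without the 2 farthest). The upper bound of that line reaches up to 1.15 of the shift seen at 500 mg/kg/day. An effect of the 500 mg/kg/day dose stays open as well: the step from 167 to 500 mg/kg/day was 0.402 of the female shift (exact permutation p = 0.127) and 1.08 of the male shift (exact permutation p = 0.0159).

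Another pattern is that hepatocyte markers were lower at 500 mg/kg/day in male adrenal, heart, spleen and testis. Lower liver expression of the same genes is argued against in heart, spleen and testis, where their median change in male liver was 0.0533, 0.249 and 0.0986 of their fall (upper bounds over resampled animals 0.456, 0.486 and 0.261), and stays open in adrenal (0.423, upper bound 0.939). A single vehicle library is argued against in adrenal, spleen and testis, which kept 0.755, 0.878 and 0.89 of the fall without the highest one (lower bounds 0.494, 0.792 and 0.652), and stays open in heart, which kept 0.544 without r04 (lower bound 0.282). Liver RNA in varying amounts may account for the pattern, since vehicle levels of liver-specific probes followed those of vehicle liver with r of at least 0.847, a correlation across genes, which are not independent replicates.

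Regrouping the same libraries at random, the real grouping included, showed how often a grouping gave as many calls as the real one. At 500 mg/kg/day 1 of 40 groupings, the real one, gave as many calls in these tables, with the real count and the highest of the others: adrenal 113 and 27 and brain 22 and 14 in females, heart 293 and 101 in females and 138 and 110 in males, kidney 526 and 332, and 117 and 96, liver 285 and 60, and 172 and 7, lung 240 and 7, and 76 and 19. The same held in ovary (17 and 15), spleen (258 and 114 in females, 428 and 55 in males), testis (332 and 99), female thymus (634 and 251) and thyroid (15 and 8 in females, 11 and 5 in males), and for 50 mg/kg/day in female kidney (201 and 44), lung (696 and 216), ovary (493 and 64) and thymus (404 and 2). Chance is thus less likely for these counts taken singly, but it is not excluded, and the margin was small in ovary, male heart and male kidney. These regroupings and those below also break up the runs of consecutive animal numbers. They thus cannot separate an effect of dose from a difference between runs. Other groupings gave as many calls in male adrenal (2 of 40 groupings, 92 real and 169 highest), male brain (2 of 40, 6 and 11) and uterus (40 of 40, 0 and 8). They did so in male thymus too (4 of 40, 89 and 353), where a regrouping with several times the real count points to a structure of the samples other than dose.

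For the genes that follow dose, only the real grouping gave as many (1 of 40 groupings) in adrenal (86 real and 27 highest in females, 73 and 4 in males), female brain (22 and 14), heart (247 and 36, 173 and 78), kidney (460 and 10, 114 and 24), liver (366 and 4, 164 and 2), lung (240 and 2, 72 and 6), ovary (117 and 4), spleen (340 and 2, 81 and 33), testis (362 and 8), thymus (595 and 54, 103 and 89) and male thyroid (180 and 61). Other groupings gave as many in male brain (2 of 40, 16 and 17), female thyroid (3 of 40, 15 and 16) and uterus (8 of 40, 3 and 5).

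For differences between the sexes chance was excluded (1 of 25 groupings) in adrenal (24 real and 1 highest), heart (63 and 49), liver (138 and 17), spleen (40 and 5) and thyroid (49 and 3), and for liver against kidney in females (101 and 50) and males (84 and 43). Other groupings gave as many for the sexes in brain (5 of 25, 2 and 10), kidney (7 of 25, 29 and 209), lung (2 of 25, 4 and 11) and thymus (2 of 25, 267 and 386). In brain and kidney, regroupings reached several times the real count, which points to a structure of the samples.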

How the results depend on the processing

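The refits with 0.05 mg/kg/day as the reference, without libraries rich in markers of another tissue and without female animals r81 to r88 were chosen only after the data were seen. No named gene reversed its direction with RLE size factors, no filter on low counts, DESeq2, vehicle and 500 mg/kg/day libraries alone or 1 animal left out. Genes named for the largest changes were taken only where all 500 mg/kg/day animals lay on the same side of the vehicle mean. The side of their animals thus follows from that choice, and leaving out 1 animal could hardly reverse them. The 3 refits above were run for counts and not for each named gene. But in several tables the larger of the higher and lower counts changed sides. At 500 mg/kg/day male lung went from 41 higher and 35 lower to 38 and 40 with RLE size factors and 43 and 58 with DESeq2, male thyroid from 6 and 5 to 15 and 51 with DESeq2, male spleen from 223 and 205 to 33 and 114 with 0.05 mg/kg/day as the reference, and female thymus from 353 and 281 to 97 and 107 without libraries rich in markers of another tissue. The genes that follow dose in male heart went from 60 rising and 113 falling to 33 and 15 without such libraries, and the sex difference in liver from 66 and 72 to 54 and 50 with no filter on low counts. Of the named genes, 153 of 153 kept their side of the threshold with RLE size factors, 148 of 153 with no filter on low counts (5 no longer called), and 146 of 149 with DESeq2 (2 no longer called, 1 newly called). With vehicle and 500 mg/kg/day libraries alone 113 of 146 did, and 33 were no longer called in fits with fewer libraries. Of 682 fits of named genes that each left out 1 animal, 566 were on the same side, 115 were no longer called and 1 was newly called. Depth limits genes near the floor, such as Acot1 with 12 counts over the female vehicle livers, and small groups limit smaller changes, since 56.1% of simulated 2-fold changes were found in male liver. Where no cause is named, the cause was not tested.

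Scaling moved few counts by more than 1.5 times, and DESeq2 moved 6 of 21 at 500 mg/kg/day. At lower doses DESeq2 moved more, 8, 11, 8, 9, 12, 13 and 13 of 21 from 0.05 to 167 mg/kg/day, so small counts there depend on the tool. RLE size factors gave 10 calls in ovary and 1 in uterus, and no filter on low counts gave 9 and 1, and 2 genes for the sex difference in lung. With DESeq2, male brain had 13, ovary 55, male thymus 142, female thyroid 53, male thyroid 66 and uterus 10. A minimum of 1.5-fold left 348 in female kidney and 145 in female lung, as it must lower counts. RLE shifted the share of higher genes by over 10 points in testis at 0.05, 0.5, 1.7 and 167 mg/kg/day, where 109 higher and 93 lower at 0.5 became 69 and 104, and among the genes that follow dose in female thymus (347 rising and 248 falling became 427 and 185) and male thyroid (59 and 121 became 32 and 130). It did so as well in 4 smaller sets, among them female thyroid at 500 mg/kg/day (9 and 6 became 9 and 3).

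Which libraries were used mattered more. With vehicle and 500 mg/kg/day libraries alone, the counts were 4 in female and 3 in male brain, 174 and 5 in heart, 347 and 10 in kidney, 114 in male liver, 17 in male lung, 3 in ovary, 289 and 5 in thymus, and 6 and 22 in thyroid. The sex difference then had 12 genes in adrenal, 2 in heart, 3 in kidney, 133 in spleen, 117 in thymus and 31 in thyroid. With all libraries kept, female brain had 13, male brain 95, male heart 80, male lung 121, ovary 4, testis 574 and male thymus 37. With 0.05 mg/kg/day as the reference, adrenal had 35 in females and 23 in males, female brain 11, female lung 8, ovary 2, spleen 116 and 147, testis 154, male thymus 153, male thyroid 2 and uterus 8. Without libraries rich in markers of another tissue, male heart had 79, male kidney 72, female thymus 204, male thymus 143, male thyroid 44 and uterus 3, and the genes that follow dose were 48 in male heart and 325 in female thymus. Without r81 to r88, ovary had 31 and female thyroid 8, and 3 genes followed dose in ovary. At 167 mg/kg/day female liver then had 189 with 153 before, kidney 23 with 34, lung 1 with 38, spleen 72 with 115 and thymus 9 with 14.

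Leaving out the 500 mg/kg/day group, which removes the largest dose, left 13 and 27 genes that follow dose in female and male adrenal, 8 in female brain, 0 and 86 in heart (0 with edgeR), 171 and 41 in kidney, 136 and 42 in liver, 5 in male lung, 239 in ovary, 125 and 13 in spleen, 149 in testis, 334 and 39 in thymus, and 1 and 98 in thyroid. A log scale of dose moved none of the 21 counts by more than 1.5 times.

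Median benchmark doses in mg/kg/day depended on the size of response that defines them. With a 10% change, they were 35.2 and 10.6 in female and male adrenal, 28.8 and 0.822 in brain, 55 and 8.00 in heart, 34.3 in female kidney, 17.3 and 23.5 in liver, 6.93 and 22.0 in lung, 6.72 in ovary, 8.88 and 25.2 in spleen, 19.1 in female thymus and 1.34 in male thyroid. With Hill and linear curves alone, they were 134 in female adrenal, 161 in female kidney, 141 in male liver, 157 in male spleen, and 137 and 158 in thymus. Without the 500 mg/kg/day group they were 21.6 and 14.2 in adrenal, 13.9 in female brain, 119 and 37 in heart, 38.2 in female kidney, 78.4 in female liver, 22.1 in male lung, 20.5 in female spleen and 28.7 in female thymus. Without r81 to r88 they were 27.4 in adrenal, 213 in kidney, 205 in lung, 81.7 in ovary and 241 in thymus, all in females. All these medians are over the trend genes chosen once with all libraries. Genes chosen anew would fall under the minimum of 10 in ovary without r81 to r88. The same holds for female heart, female brain and male lung without the 500 mg/kg/day group.

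With an estimated correlation, the gene lists called were 1 in male adrenal, 2 in female brain, 3 and 1 in female and male heart, 4 and 1 in kidney, 5 and 4 in liver, and 0 in female adrenal, male brain, lung, ovary, spleen, testis, thymus, thyroid and uterus, 21 in all with 113 before. Camera with the preset correlation is the other count given.

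Leaving out 1 animal of the 500 mg/kg/day group at a time gave these ranges of calls: male adrenal 41 to 101, brain 11 to 26 in females and 0 to 5 in males (edgeR), heart 185 to 283 and 16 to 168, male kidney 39 to 151, liver 188 to 340 and 75 to 157, lung 107 to 198 and 18 to 58, ovary 4 to 17, spleen 135 to 323 and 205 to 392, testis 206 to 283, thymus 185 to 719 and 17 to 125, thyroid 6 to 21 and 0 to 14, and uterus 0 to 4. Female adrenal (82 to 102) and female kidney (405 to 526) stayed within 1.5 times. The difference between liver and kidney ranged from 25 to 82 in males. For the sex difference, where these fits used vehicle and 500 mg/kg/day libraries alone, the ranges were 6 to 15 in adrenal, 1 to 6 in heart, 3 to 6 in kidney, 68 to 233 in liver, 0 to 9 in lung, 93 to 164 in spleen, 56 to 151 in thymus and 13 to 32 in thyroid. Median benchmark doses ranged from 41.1 to 187 in female brain, 47.3 to 109 in female thymus, 19.8 to 36.4 in male adrenal, 55.2 to 142 in male heart and 71.9 to 106 in male liver.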

Other observations

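PPAR alpha targets and xenobiotic receptor targets rose in liver of both sexes and in female kidney, with calls that held with an estimated correlation. The steroid genes Cyp17a1 and Srd5a1 moved in opposite directions in female liver, and several genes higher in male liver fell in males.

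In some libraries markers of a tissue other than the labelled one stood out, given here as log2 units above the median of the table. Female kidney r83 at 50 mg/kg/day held T-cell markers at 4.44, male thymus r11 at 0.05 mg/kg/day skeletal muscle markers at 5.66, and female thymus r84 B-cell markers at 3.57. Adipocyte markers stood at 4.17 in male kidney r27 and 3.45 in uterus r75, and hepatocyte markers at 3.72 in female thyroid r79, 3.16 in female heart r84 and 2.84 in uterus r93.

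Values of liver and kidney libraries with the same animal number, taken as differences from the dose mean and compared across genes, had a median Pearson r of 0.153 in females and 0.15 in males. Libraries of different animals had -0.003 and -0.004. Genes are not independent replicates, so no test is given.

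On simulated doses, curve fits returned a median benchmark dose of 50.3 for a linear curve with a true value of 50, 24.1 for a Hill curve with 20 and 194 for a power curve with 200.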
